A study of Mus musculus with 5 samples.

How the data were processed

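RNA was extracted from 6K sorted cells per sample and libraries were made by Smart-seq2, per the labels' protocols, a full-length method whose standard form does not mark strand. Such amplification from few cells adds noise between libraries. The deposited files give, for each of the 5 samples, raw counts per gene as whole numbers and, in a second file, TPM, transcript levels scaled to library size and length, as the authors normalized them. The submitters' processing notes name FastQC 0.11.5, Trimmomatic, TopHat2 2.1.1, RSEM 1.2.31, HTSeq and DESeq2, and the genome build mm9. Which of these tools made which values, and with which settings, is not given in the sources used here.

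Each file holds 33924 entries, of which 30 name no gene. These took between 0.216% and 0.269% of the counts and were left out of library sizes and tests. Gene identifiers and symbols were used as the files give them, and no coordinates are given because the reference at hand, GENCODE M21 on GRCm38, is of another build. By identifier, 13206 of the tested genes could be placed in it on a nuclear chromosome. That reference served for gene length, GC content, gene order and sequence matches of pseudogenes.

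Samples were grouped by their labels as 2 WT and 3 dKO. Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr (13696 genes kept), robust quasi-likelihood fits and Benjamini-Hochberg adjusted p under 0.05, with all 5 samples and no covariate. CPM values are scaled by TMM, and the common dispersion was 0.461, a biological coefficient of variation of 67.9%. The 35 gene lists and the tests were fixed before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the lists. An estimated correlation and the fry rotation test were run beside it. With the preset correlation 20 lists were called, with an estimated correlation 0, and with fry 4 (DNA replication lower; immediate early, megakaryocyte and erythroid, adhesion and homing higher). Of the list entries 1174 matched a symbol in the files, 10 matched through an Ensembl identifier, 7 repeated another member and 4 had no match.

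Genes named in the text are Lrp5 and Lrp6, up to 12 genes per direction past the threshold, the 5 with the smallest p per direction where fewer than 5 passed, up to 4 members per list with the smallest p, and the sex-linked and sort gate genes. Other genes are said to be chosen after their values were seen. 2 list members that this rule would name are not reported here.

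The tests were checked on simulated counts made from the means, the library sizes and edgeR's dispersion estimates of these samples. In 5 simulations of 13696 genes with 200 changed, edgeR recovered 6.80% of 2-fold and 49.8% of 4-fold changes with 8.41% of its calls false, and DESeq2 20.0% and 67.8% with 44.8% false. A list shifted by -0.6 was called by camera in 5 of 5 simulations, and 2 calls were made in all among the unshifted lists. Each gene was simulated independently, whereas the correlation estimated between genes of the real lists reached 0.749, for ribosomal proteins. The simulations therefore cannot show how often camera with the preset correlation calls unshifted lists in these data. Libraries of the same group differed far beyond sampling noise, with a chi-square per degree of freedom of 107 to 174, so none was counted as a duplicate.

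Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, other scalings (RLE and upper quartile), no filter on low counts, a filter of 5 CPM in 2 libraries, limma on log2 TPM with a pseudocount of 1 or 0.1, the replicate number as a block, and each library left out in turn. Where WT is left with 1 library, that sample is assumed to vary like the others. With library totals of 16028512 to 28027458 counts, a gene with no count has an upper limit of 0.107 to 0.187 CPM (3 counts per library). These limits use the totals without TMM scaling and cover counting error only.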

Results

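Gene expression was measured by bulk RNA sequencing in mouse haematopoietic stem cells sorted from bone marrow as lineage-negative, Sca1-positive, c-Kit-high cells lacking CD34 and Flt3. The 5 libraries came from 8-week-old mice, 2 from wild type (WT) animals and 3 labelled as doubly deficient (dKO) for Lrp5 and Lrp6, the co-receptors through which Wnt ligands act on beta-catenin. The labels give the dKO genotype as Vav-cre with Lrp5 fl/fl and Lrp6 fl/fl, a Cre transgene with floxed copies of both genes. They name Cre in that group only, so an effect of the transgene cannot be told apart from loss of the genes. Each library started from 6K cells. Library totals ranged from 16028512 counts in dKO replicate 2 to 28027458 in WT replicate 2. WT replicate 1 held 26242672 counts, dKO replicate 1 25216810 and dKO replicate 3 26869348. Between 12894 and 16098 genes had at least 1 count per library, the lowest number being that of dKO replicate 2. That library also stood apart in log2 CPM, the counts scaled to library size, where its highest correlation across genes with any other library was 0.851, while the other 4 libraries correlated at 0.883 or more. The labels do not say whether each library came from a separate mouse, so edgeR's p-values measure only the spread between these samples. Camera with the preset correlation sets the genes of a list against the other genes. Its p-values therefore do not measure how well the libraries of a group agree. For the respiratory chain list, camera gave an adjusted p of 1.09e-11 and fry, which uses the spread between samples, gave 0.187.

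The targeted genes came first, as a check of the labels. Lrp6 had 660 and 232 counts in the WT libraries and 790, 260 and 767 in the libraries labelled dKO, a log2 fold change of 0.51 (95% interval -0.77 to 1.79, adjusted p = 0.842 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Lrp5 was near the detection limit, with 7 and 32 counts in WT and 37, 2 and 71 in the libraries labelled dKO, a log2 fold change of 0.83 (95% interval -3.47 to 5.12, adjusted p = 0.942 by the same edgeR test). The value for Lrp6 was -0.04 without WT replicate 2, and that for Lrp5 was -0.05 without dKO replicate 3. Neither gene was lower in the libraries labelled dKO. A count over a whole gene cannot show the loss of a deleted exon, so these counts do not settle the genotype, and every direction below is drawn from the labels alone.

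**Figure D1:**
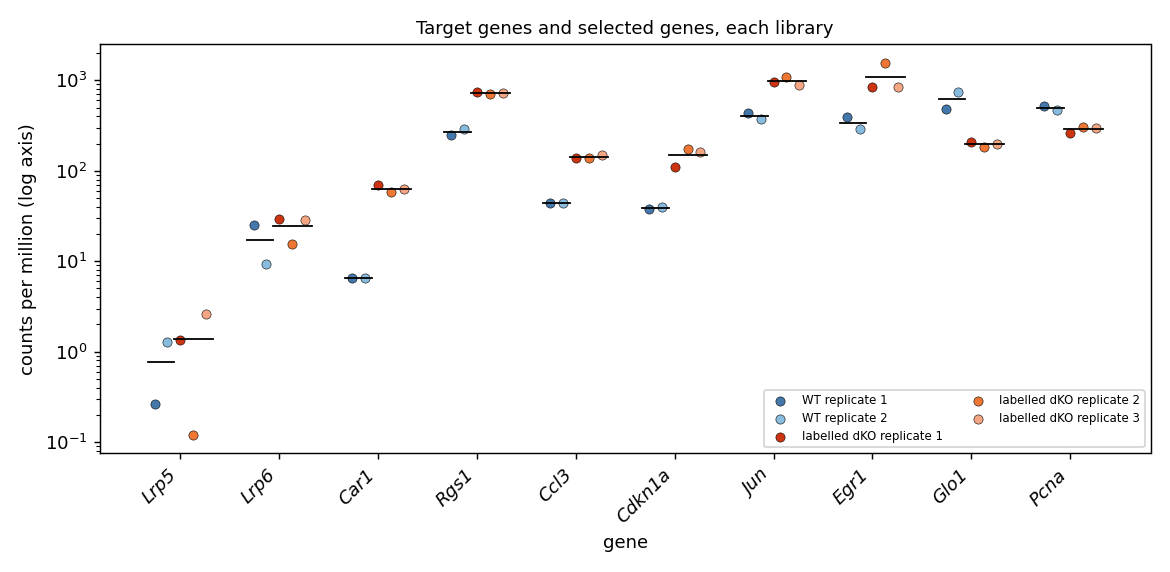
CPM on a log axis for Lrp5, Lrp6 and 8 other genes in each of the 5 libraries, with a horizontal line at each group's mean. Car1 lay at 6.57 and 6.45 CPM in WT and between 58.2 and 69.9 CPM in the libraries labelled dKO, while the points of Lrp5 and Lrp6 overlap between the groups.

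The comparison asks which genes differ between the libraries labelled dKO and WT. The genes with the smallest p-values among the higher ones were Car1, a carbonic anhydrase of early erythroid cells, the G protein signalling regulator Rgs1, the chemokine Ccl3, the cyclin-dependent kinase inhibitor Cdkn1a and the transcription factor Jun. Car1 measured 6.51 ± 0.0875 CPM in WT (SD, n = 2) and 63.6 ± 5.88 CPM in the libraries labelled dKO (SD, n = 3). Ccl3 measured 44.5 ± 0.118 and 142 ± 7.70 CPM, Cdkn1a 38.8 ± 1.78 and 148 ± 32.9 CPM, and Rgs1 270 ± 27.1 and 722 ± 20.3 CPM. The lower genes with the smallest p-values were the glyoxalase Glo1, at 618 ± 185 CPM in WT and 196 ± 11.7 CPM in the libraries labelled dKO, the uncharacterised gene 5730437N04Rik (log2 fold change -1.48), and the pseudogenes Gm9825, Gm3608 and Gm15487 (log2 fold changes -6.91, -6.27 and -6.24). Counts of these pseudogenes are uncertain because each is over 99% identical to an expressed gene, at 99.4% for Gm9825 and Rnps1, 99.5% for Gm3608 and Capza1 and 99.8% for Gm15487 and Atp6v0c.

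No single gene passed the adjusted threshold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 13696 tested genes were called higher and 0 lower, the smallest adjusted p being 0.178 for Car1, although 1388 genes had an unadjusted p under 0.05 (677 higher, 711 lower), against 685 given by chance. DESeq2 called 154 genes higher and 91 lower, and limma-voom called 0. DESeq2's calls in these data need caution. On simulated counts for this comparison 44.8% of its calls over 5 simulations of 13696 genes were false, against 8.41% for edgeR. In these simulations edgeR recovered 6.80% of genes changed 2-fold and 49.8% of those changed 4-fold. The counts were drawn with edgeR's own dispersion estimates, and the number of changed genes was set at 200. They therefore do not give the false share of DESeq2's calls in the real data. Without WT replicate 2, DESeq2 called 65 genes higher and 7 lower. Without WT replicate 1 it called 203 genes lower, and without dKO replicate 3 it called 77 higher and 143 lower. In 13.7% of genes every library labelled dKO lay above every WT library and in 15.6% below, where chance gives 10% each.

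Genes of DNA replication, growth and respiration were lower as groups in the libraries labelled dKO. In the DNA replication list 47 of 51 tested members had a lower value, with a median log2 fold change of -0.66 (camera adjusted p = 1.09e-11; adjusted p = 0.234 with an estimated correlation). Pcna, the clamp that holds DNA polymerase, measured 491 ± 35.0 CPM in WT and 290 ± 22.7 CPM in the libraries labelled dKO, and Rpa2, Dtl and Mcm4 had log2 fold changes of -0.82, -0.91 and -0.77. The respiratory chain list had 74 of 77 members lower with a median of -0.49 (camera adjusted p = 1.09e-11; adjusted p = 0.408 with an estimated correlation), among them Atp5g1 (-0.95), cytochrome c, Cycs (-1.15), Ndufv2 (-0.73) and Cox5b (-0.68). Ribosome biogenesis had 42 of 44 members lower with a median of -0.55 (camera adjusted p = 1.58e-08; adjusted p = 0.402 with an estimated correlation), with Npm1 at -0.94, Nhp2 at -0.88 and Fbl at -0.83. Ribosomal protein genes had 72 of 75 members lower with a median of -0.34 (camera adjusted p = 6.33e-07; adjusted p = 0.524 with an estimated correlation), with Rpsa at -0.55. After a trend on GC content and transcript length over all genes was removed, the distance of the ribosomal protein median from that of all genes fell from -0.37 to -0.16. Adjusted over the list alone, 18 replication genes passed edgeR's test as lower and 0 genes of the other 3 lists did, against 0 over all genes tested.

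The mitosis list had 46 of 55 members lower with a median of -0.43 (camera adjusted p = 2.81e-05; adjusted p = 0.493 with an estimated correlation), including the checkpoint kinase Bub1 (-1.40), Nuf2 (-1.01), Ckap2l (-1.12) and cyclin Ccna2 (-0.82). The heat shock and unfolded protein list had 23 of 31 lower with a median of -0.59 (camera adjusted p = 0.0118; adjusted p = 0.524 with an estimated correlation), but its members went apart: Asns, Hspd1 and Sdf2l1 had log2 fold changes of -1.60, -0.85 and -1.59 and the cytosolic chaperone partner Dnajb1 0.79. Adjusted over the list alone, 0 mitosis genes and 6 heat shock genes (5 lower, 1 higher) passed edgeR's test, against 0 over all genes. WT replicate 2 carried far more transcripts of granulocyte progenitors than the other libraries. Mpo, myeloperoxidase, stood at 21486 CPM there, at 3447 CPM in WT replicate 1 and between 6031 and 9684 CPM in the libraries labelled dKO, and the chaperone Hspa5 stood at 4639 CPM against 1871 CPM in WT replicate 1. Both genes were chosen after their values were seen. Without WT replicate 2 the mitosis median was -0.03 (camera adjusted p = 0.505) and the heat shock median 0.00 (camera adjusted p = 0.647), so neither call was made without that library. Heat shock was also not called without dKO replicate 3 (camera adjusted p = 0.204). Without WT replicate 2 the ribosomal protein median was -0.17 and that of ribosome biogenesis -0.36, and without WT replicate 1 the mitosis and heat shock medians were -0.77 and -0.89.

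**Figure D2:**
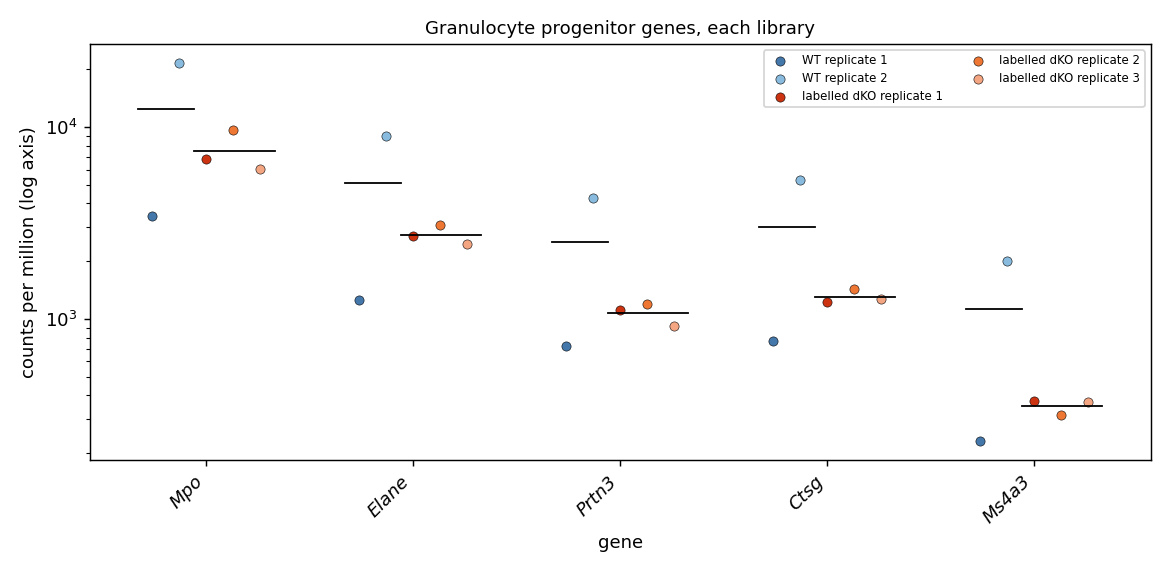
CPM on a log axis for 5 granulocyte progenitor genes in each library, with a horizontal line at each group's mean. The genes were chosen after their values were seen. WT replicate 2 lies above the other 4 libraries for each gene, with Elane at 8998 CPM there and between 1248 and 3086 CPM elsewhere.

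Immediate early genes, which respond within minutes to stimulation, were higher as a group in the libraries labelled dKO. Of 26 tested members 25 had a higher value, with a median log2 fold change of 1.04 (camera adjusted p = 3.70e-10; adjusted p = 0.234 with an estimated correlation), and 13 passed edgeR's test adjusted over the list alone, against 0 over all genes. Jun measured 407 ± 42.4 CPM in WT (SD, n = 2) and 989 ± 104 CPM in the libraries labelled dKO (SD, n = 3), and the nuclear receptor Nr4a1 82.3 ± 54.0 and 940 ± 492 CPM. Btg2 and Klf6 had log2 fold changes of 1.90 and 1.08, whereas Fos, named after its value was seen, had 0.14. The NF-kappaB list had 20 of 30 members higher with a median of 0.999 (camera adjusted p = 0.000162; adjusted p = 0.343 with an estimated correlation), and 6 passed adjusted over the list alone. Among its 4 genes with the smallest p were Ccl3, Nfkbiz (1.82) and the feedback inhibitor Nfkbia (1.33).

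TGF-beta and BMP pathway genes had a median log2 fold change of 0.71 with 25 of 29 higher (camera adjusted p = 3.58e-05; adjusted p = 0.343 with an estimated correlation), led by the inhibitors Skil (2.42) and Smad7 (2.44), the 2 genes that passed adjusted over the list alone. Notch pathway genes had a median of 0.72 with 17 of 20 higher (camera adjusted p = 0.00269; adjusted p = 0.357 with an estimated correlation). The Notch target Hes1 had a log2 fold change of 3.22 and was the 1 gene that passed adjusted over the list alone. Notch was not called without WT replicate 2 (camera adjusted p = 0.114) or without dKO replicate 2 (camera adjusted p = 0.0513), and its median was 1.08 without WT replicate 1.

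Genes that mark haematopoietic stem cells were also higher as a group. Of 52 tested members 46 had a higher value, with a median log2 fold change of 0.62 (camera adjusted p = 2.11e-07; adjusted p = 0.343 with an estimated correlation), and 8 passed edgeR's test adjusted over the list alone, against 0 over all genes. Mmrn1, a platelet-lineage adhesion protein, measured 128 ± 28.0 CPM in WT and 311 ± 61.3 CPM in the libraries labelled dKO, and the RNA-binding protein Msi2 43.6 ± 6.51 and 113 ± 25.5 CPM. The median was 0.37 without WT replicate 2 and 1.0 without WT replicate 1. The quiescence list had 26 of 31 higher with a median of 0.56 (camera adjusted p = 0.000173; adjusted p = 0.343 with an estimated correlation), led by Cdkn1a, Btg2 (1.90), Klf6 (1.08) and Ier2 (0.96), and 4 passed adjusted over the list alone. Both lists share members with the immediate early list. Without the 3 shared genes the stem cell list had an adjusted p of 3.34e-06 by camera with the preset correlation and 0.203 by fry. Without its 7 shared genes the quiescence list had 0.0115 and 0.228. By camera the quiescence list then had 0.0783 and 0.137 when WT replicate 2 or dKO replicate 3 was also left out.

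Surface markers of the sort gate had a median log2 fold change of 0.87 in 10 tested genes (camera adjusted p = 0.0346; adjusted p = 0.408 with an estimated correlation), a call not made without WT replicate 2 (camera adjusted p = 0.537), dKO replicate 1 (0.0583), dKO replicate 2 (0.108) or dKO replicate 3 (0.0780). The median was 0.30 without WT replicate 2, 0.48 without dKO replicate 2 and 0.38 without dKO replicate 3. Of these genes 8 were higher and 2 lower. Kit had a log2 fold change of 0.84, Flt3 0.91, Ly6a, which encodes Sca1, -0.03, and Itgam 1.57. The list mixes markers that the gate selected for, such as Kit, with markers that it excluded, such as Flt3. Its median therefore has no single meaning for the gate. Cd34 transcripts were abundant in every library, from 761 CPM in WT replicate 2 to 1212 CPM in WT replicate 1, and Flt3 ranged from 116 to 360 CPM, although the gate excluded both proteins at the surface.

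None of the 4 Wnt lists was called lower. Wnt transducers had 26 of 34 members higher with a median log2 fold change of 0.26 (camera adjusted p = 0.0326; adjusted p = 0.343 with an estimated correlation), led by the corepressor Tle2 (4.25), the 1 gene passing adjusted over the list alone, then Crebbp (0.91), Apc (1.37) and Tcf7l2 (0.95). That call was not made without WT replicate 2 (camera adjusted p = 0.195), dKO replicate 1 (0.0629), dKO replicate 2 (0.0844) or dKO replicate 3 (0.0780). After a trend on GC content and transcript length over all genes was removed, the transducer median was -0.03 and the receptor median 0.03, against -0.14 for all genes. The distance of the transducers from all genes fell from 0.23 to 0.11 and that of the receptors from 0.32 to 0.17. Wnt target genes were not called, at a median of 0.51 over 22 genes (camera adjusted p = 0.140), 0.28 without dKO replicate 3 and 0.26 after the trend was removed (a distance from all genes of 0.41 against 0.48 before), with Jun (1.28) and Plaur (0.71) on one side and Birc5 (-0.75) on the other. Axin2, a direct target, had 2 counts in dKO replicate 1 and 0 in the other libraries, a level too low to test. Myc and Ccnd1, named after their values were seen, had log2 fold changes of 0.09 (95% interval -0.35 to 0.53) and 0.04 (-1.52 to 1.60). Lef1 and Tcf7, also targets and chosen in the same way, had low counts. Lef1 had 23 and 68 counts in WT and 106, 75 and 311 in dKO replicates 1, 2 and 3. Tcf7 had 79 and 54 counts in WT and 16, 229 and 81 in those dKO replicates. Wnt receptors, with a median of 0.35 over 19 genes, and ligands with their regulators, with 0.27 over 6, were not called (camera adjusted p = 0.592 and 0.587). The receptor median was 0.76 without WT replicate 1, -0.04 without WT replicate 2 and -0.05 without dKO replicate 3, and the ligand median 1.28 without WT replicate 1 and -0.29 without dKO replicate 1. Relative to each gene's mean over the libraries, receptors averaged -1.41 log2 CPM in dKO replicate 2. They averaged 0.16 and 0.97 in dKO replicates 1 and 3, and 0.27 and 0.002 in WT replicates 1 and 2. Some receptor genes, such as Ryk and Tspan12, had 0 counts in dKO replicate 2.

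**Figure D3:**
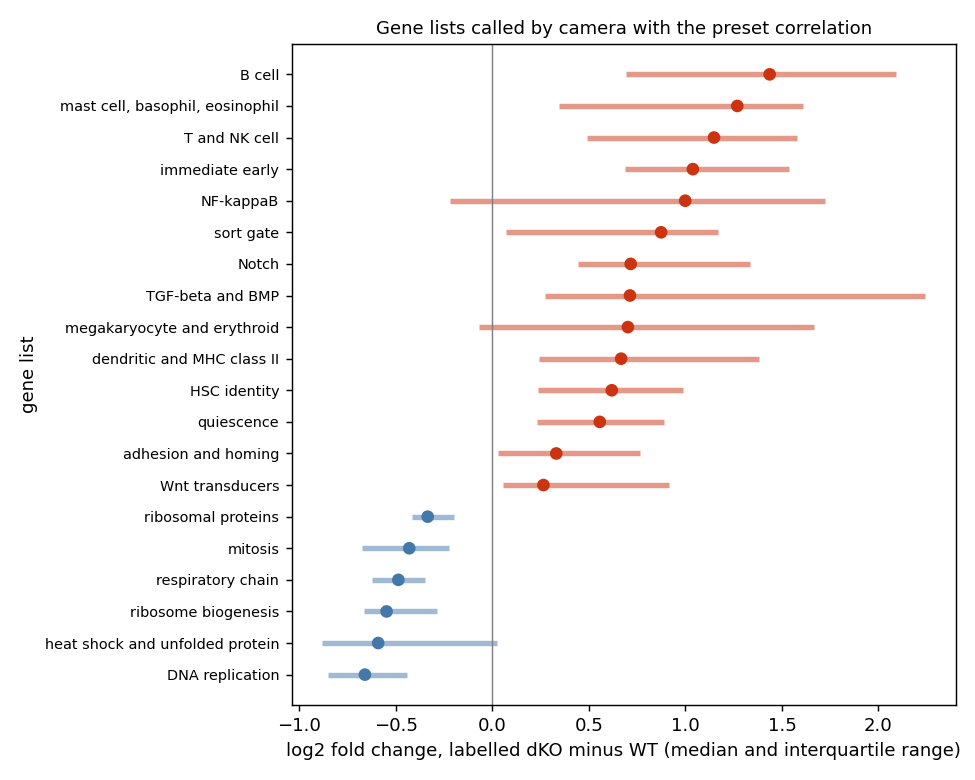
Median log2 fold change (points) and interquartile range (bars) of the 20 gene lists called by camera, the libraries labelled dKO against WT. The 14 lists with higher values run up to a B cell median of 1.44 and the 6 with lower values down to a DNA replication median of -0.66; with an estimated correlation 0 of the 20 were called.

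Transcripts of several differentiated lineages were higher as groups in the libraries labelled dKO. The megakaryocyte and erythroid list had a median log2 fold change of 0.70 with 21 of 30 higher (camera adjusted p = 0.000127; adjusted p = 0.234 with an estimated correlation), led by Car1, the Rh protein Rhag (5.11), Car2 (0.82) and Aqp1 (1.74). The list of mast cells, basophils and eosinophils had a median of 1.27 with 14 of 17 higher (camera adjusted p = 0.000295; adjusted p = 0.343 with an estimated correlation), with the proteases Prss34 at 34.3 ± 27.8 CPM in WT and 258 ± 201 CPM in the libraries labelled dKO and Cpa3 at 39.2 ± 1.65 and 93.5 ± 32.1 CPM. It was not called without WT replicate 1 (camera adjusted p = 0.0560). B cell genes had a median of 1.44 with 17 of 19 higher (camera adjusted p = 0.000162; adjusted p = 0.408 with an estimated correlation), among them Blnk (2.95), the transcription factor Ebf1 (3.99), Cd79a (2.09) and Vpreb1 (1.86). The B cell median was 2.68 without WT replicate 1 and 0.99 without WT replicate 2. It was 1.82, 1.71 and 1.08 without dKO replicates 1, 2 and 3, so its size depended on which libraries were kept. Adjusted over the list alone, 1, 6 and 0 genes of these lists passed.

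Dendritic and MHC class II genes had a median of 0.67 with 16 of 19 higher (camera adjusted p = 0.0118; adjusted p = 0.408 with an estimated correlation), with H2-Eb1 at 1.93 and H2-Aa at 1.25. T and NK cell genes had 1.15 (camera adjusted p = 0.0473; adjusted p = 0.408 with an estimated correlation) although Nkg7 had -1.02 and Rora 1.38, and adhesion and homing genes 0.33 (camera adjusted p = 0.0473; adjusted p = 0.343 with an estimated correlation), with Itgav at 1.18 and Cdc42 at -0.43. Dendritic genes were not called without WT replicate 2 (camera adjusted p = 0.114) or dKO replicate 3 (0.0825) and had a median of 1.31 without WT replicate 1. The call was not made for T and NK genes without WT replicate 2 (0.324) or dKO replicate 3 (0.204; median 0.47), and their median was 0.69 without dKO replicate 1. It was not made for adhesion genes without WT replicate 1 (0.129), WT replicate 2 (0.1104), dKO replicate 2 (0.109; median 0.20) or dKO replicate 3 (0.0884). With all libraries, T and NK genes were also not called under upper-quartile scaling (0.0521), a filter of 5 CPM in 2 libraries (0.0561) or log2(TPM + 1) (0.0740), nor adhesion genes under that filter (0.0561). Neutrophil and monocyte genes were not called (median -0.67, camera adjusted p = 0.671), but were called lower without WT replicate 1 (median -1.40) and higher without WT replicate 2 (median 0.72). Endothelial and stromal genes were not called either (median 0.69, camera adjusted p = 0.167), with medians of 1.22 without WT replicate 2, 0.45 without dKO replicate 1 and 0.44 without dKO replicate 3.

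Of the remaining lists none was called by camera with all 5 libraries. The p53 targets had a median log2 fold change of 0.25 (adjusted p = 0.0544), with Plk2 at 1.99 beside Cdkn1a, and were called without WT replicate 1 (median 0.62, adjusted p = 0.0454). Without dKO replicate 3 their median was 0.39. Interferon genes had -0.01 (adjusted p = 0.890) and were called higher without WT replicate 1 (median 0.52) and lower without WT replicate 2 (median -0.19). Glycolysis had -0.21 (adjusted p = 0.228; -0.03 without WT replicate 2 and -0.33 without dKO replicate 1), redox genes -0.20 (0.168; -0.08 without WT replicate 2), cholesterol synthesis 0.04 (0.609; 0.26 without dKO replicate 1 and -0.19 without dKO replicate 3), apoptosis -0.08 (0.523; 0.10 without WT replicate 2), multipotent progenitor genes 0.01 (0.277; 0.25 without WT replicate 2) and mitochondrially encoded genes 0.01 (0.439; 0.22 without dKO replicate 2 and -0.21 without dKO replicate 3). These 4 medians lie near 0 and turned sign with 1 or more libraries left out. Camera's direction was opposite to that of the median for cholesterol synthesis, apoptosis, interferon and mitochondrially encoded genes. Common reference genes had -0.36 (adjusted p = 0.0699, and 0.0380 without WT replicate 1), with Pgk1 at -0.72. Their median was -0.12 without WT replicate 2 and -0.20 without dKO replicate 1. The sex-linked list was not called (median 0.45, adjusted p = 0.309), with medians of 0.69 without WT replicate 1, 0.29 without WT replicate 2 and 0.22 without dKO replicate 1. Ddx3y lay between 67.6 and 184 CPM and Xist below 1 CPM in every library, so all 5 had a male pattern. After the trend on GC content and length was removed, distances from all genes fell from -0.39 to -0.22 for reference genes, from -0.23 to -0.14 for redox genes and from 0.42 to 0.21 for the sex-linked list.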

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

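DESeq2 without each library, thinning to equal library totals, and lists without their immediate early members were chosen after seeing the data. The absence of single-gene calls by edgeR held under RLE and upper-quartile scaling, the 5 CPM filter and limma-voom, with 0 higher and 0 lower; genes at an unadjusted p under 0.05 numbered 1375, 1353, 1226 and 1622 there and 1388 in edgeR's fit with TMM. Elsewhere DESeq2 gave 154 higher and 91 lower, no filter 5 and 3, log2(TPM + 1) 3 and 2, and log2(TPM + 0.1) 2 higher. Leaving out 1 library gave 0 to 2 higher and 0 to 2 lower, the 2 and 2 without WT replicate 1; the cause was not tested. DESeq2 so treated gave 65 to 212 higher and 7 to 203 lower. Lrp5 ranged from -0.0497 (without dKO replicate 3) to 2.35 and Lrp6 from -0.0378 (without WT replicate 2) to 1.39. Lists called numbered 20, 0 with an estimated correlation, 4 by fry, 20 with RLE, 19 with upper-quartile scaling or log2(TPM + 1), 18 with the 5 CPM filter and 14 to 22 with 1 library left out; 11 of the 20 were called in the same direction in each of those 5 fits (7 higher, 4 lower). The median of all genes moved from 0.04 to 0.10 with no filter, 0.14 with TPM, 0.11 without WT replicate 1 and -0.06 with a replicate block, and lay between -0.01 and 0.05 otherwise. Deviations from the group mean correlated at 0.03 and 0.05 in the 2 pairs of libraries with equal replicate numbers. The deviations of the WT libraries mirror each other, so these values are not independent and cannot exclude a shared batch. With a replicate block 1 gene was higher, 0 lower, and Lrp5 was -0.40. That fit called 14 lists (not Wnt transducers, sort gate, heat shock, adhesion, T and NK or dendritic genes). Depth limits genes such as Lrp5, at 2 to 71 counts.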

Other observations

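The tests of heat stress, of WT replicate 2, of chromosome segments and of B cell genes below, the genes named in the next paragraph apart from Ctla2a, and the pseudogenes Gm11847 and Pcna-ps2, were chosen only after values had been seen, and bootstrap intervals were added after a first look at these tests. The tests of depth, GC content, parent genes and sample splits were written before their results. Bootstrap intervals resample the genes of a list, not the libraries, so they do not measure the spread between samples.

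Among single genes, 18 were called by DESeq2 with all 5 libraries and with each library left out in turn, while edgeR's quasi-likelihood test called 0 genes with 1388 at an unadjusted p under 0.05. Besides immediate early genes they include the nuclear noncoding RNAs Malat1 and Neat1, at log2 fold changes of 1.34 and 1.73, and the splicing-related genes Clk1, Ccnl1 and Srrm2, at 1.66, 1.27 and 1.28. Malat1 stood at 1163 and 940 CPM in WT and at 2278, 2502 and 3217 CPM in the libraries labelled dKO. Ran, a GTPase of nuclear transport, stood at 1439 and 1957 CPM in WT and between 795.5 and 834 CPM in the libraries labelled dKO. Ctla2a and lymphotoxin beta, Ltb, had log2 fold changes of 1.35 and 1.38. The serine synthesis enzyme Psat1, not among the 18, had -1.15. Of 5 genes abundant in mature B cells 4 were tested and 1, Cd74, lay higher in every library labelled dKO than in both WT libraries, with a log2 fold change of 1.13. Cd79b had -0.08 with an upper 95% limit of 0.617, below the B cell list's median of 1.44, and Igkc spanned 462 to 3745 CPM in the libraries labelled dKO against 529 and 50.7 CPM in WT. These genes disagree, so a share of mature B cells, which a gate for lineage-negative cells should have removed, stays open.

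The first pattern is the higher level of immediate early and NF-kappaB genes. The immediate early median was 1.05 after every library was thinned to the smallest total, against 1.04 before. Random thinning keeps the expected share of each gene in its library, so the median could hardly have moved. The test therefore does not decide whether depth had a part. A trend on GC content and transcript length does not account for the pattern. After its removal the median was 0.77 (95% bootstrap interval 0.69 to 1.09), against -0.14 for all genes. The 9 cytosolic heat shock genes went both ways, 3 higher and 6 lower, with a median of -0.29 and a 95% bootstrap interval of -0.61 to 1.002. An interval this wide does not decide whether heat stress had a part. Handling stress that leaves these genes unchanged would not show in them, so handling stays open too. A difference in how the cells were sorted, a different nuclear share of the RNA, and the genotype named by the labels all stay open and were not tested.

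The second pattern is the lower level of replication, growth and respiration genes, set against the granulocyte progenitor transcripts of WT replicate 2. Without that library the DNA replication median was -0.59 and the respiratory chain median -0.34 (95% bootstrap intervals -0.73 to -0.46 and -0.37 to -0.25). With all libraries they were -0.66 and -0.49, so part of each difference was present without WT replicate 2. That remainder rests on WT replicate 1 as the only WT library, and the intervals cover the spread between genes, not between libraries. Both lists stayed called by camera with the preset correlation, while with an estimated correlation neither was called even with all libraries (adjusted p = 0.234 and 0.408). The ribosome biogenesis median was -0.36 with a 95% bootstrap interval of -0.47 to -0.25, which leaves its share from that library open. The mitosis and heat shock medians were -0.0298 and 0.000225, so granulocyte progenitors in WT replicate 2 are a candidate source of those differences, as a hypothesis from 1 library, since a gate for Sca1-positive cells lacking CD34 should have kept such cells out.

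The third pattern is a set of genes nearly on in one group and off in the other: Glo1 in part, and the pseudogenes Gm9825, Gm3608, Gm15487, Gm11847 and Pcna-ps2. A like change in the counts of the parent gene was absent for 5 of 5 pseudogenes. Their best-matching gene moved the other way or by far less, as with Pcna-ps2 at 5.64 and Pcna at -0.76. Whether reads of a parent gene were assigned to its copy in one group only was not tested. Glo1 is known to vary in copy number between mouse strains, but genes with p under 0.05 did not crowd along the chromosomes: the fullest window of 20 neighbours held 8, with a permutation p of 0.804, which leaves a segment with few affected genes untested. Among the 100 tested genes nearest to Lrp5 such genes numbered 19 and among the 100 nearest to Lrp6 11, where neighbourhoods elsewhere had a median of 10 and a 95th percentile of 16, so the excess lay near Lrp5. Together they made 30 of 200 against 10.2% elsewhere (Fisher's exact test, two-sided, p = 0.0337, unadjusted as 1 of 2 strain tests; chance p = 0.0325 against random neighbourhoods), yet 1 of the 9 other sample splits gave a higher ratio, 1.61 against 1.47, a comparison required only after the first values were seen. None of the 5 genes of this pattern that could be placed lies among those neighbours, so these neighbourhoods are not where they sit. Of Glo1, Gm3608 and Gm11847, 0 lie on the chromosome of Lrp5 or Lrp6, so a strain segment flanking either gene does not hold them. For Gm3608 and Gm11847 this concerns the annotated copy only. Their reads may stem from a closely matching gene, whose position was not checked, so the source of these counts stays open. Pcna-ps2 is the gene ranked 171 by distance from Lrp5 and Gm15487 the one ranked 571 from Lrp6, and Gm9825 was not placed, so for these 3 a longer flanking segment cannot be told apart from chance. Strain differences elsewhere in the genome, also around the Vav-cre transgene, stay open.

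The 5 libraries can be split into 2 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1388 genes at p under 0.05, and the highest of the other 9 gave 993. For gene lists called by camera the real split gave 20 and the highest other 17, which came from setting dKO replicates 2 and 3 against the rest. In each case 1 of the 10 splits, the real one, gave a result as large.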
